A study of Mus musculus with 2 samples.

How the data were processed

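Total RNA sequencing with ribosomal RNA depletion was done on RNA of the nucleoplasmic fraction of mouse bone marrow-derived macrophages, per the labels. These are primary cells of the C57BL/6J strain, grown from bone marrow and stimulated with Lipid A, the membrane-anchored part of bacterial lipopolysaccharide, at 100 ng/ml for 30 min. The series holds 1 group of 2 libraries, labelled biological replicates 1 and 2. The sample descriptions name the fraction as nucleoplasmic, and other labels name it as nuclear. The starting RNA was 1 µg for replicate 1 and 500 ng for replicate 2. Both replicates cite the same donor entry and different biosamples. Apart from the word biological, nothing in the labels says that the cultures were separate, so the spread between the libraries may be technical.

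Each library had 1 gene table and 2 transcript tables on mm10 with GENCODE M21, per the labels in the deposited text files. The gene table and the first transcript table were derived from a transcriptome alignment, and the second transcript table was derived from the reads directly, per the same deposited text files. The tools are not given in the sources used here; the column names are those that RSEM and kallisto write. The deposited gene tables give expected counts, TPM and FPKM, and credibility bounds whose level is not stated, per the file headers. The deposited first transcript table also gives the percent of a gene's expression in each transcript, per the file headers. The second deposited transcript table gives estimated counts and TPM, per the file headers. FPKM and the isoform percent columns as deposited were not used for any value. Whether counting used strand is not given in the sources used here, so reads of overlapping genes on opposite strands are reported as uncertain.

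All 55536 annotated gene IDs of the gene tables were found in the GENCODE M21 annotation, which also gave symbols, classes and coordinates. Spike-in entries and 26248 numbered features without a gene name stayed out of library sizes and list tests; they held 1.19% of the expected counts in replicate 1 and 0.213% in replicate 2. Expected counts summed to 16037242 in replicate 1 and 14906686 in replicate 2. The second transcript tables summed to 22142536 and 25852914 estimated counts. A count of 0 allows up to 3 counts, which is 1.87e-05% of replicate 1 and 2.01e-05% of replicate 2. These limits and the 95% Wilson intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

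With 1 group there was no comparison of conditions and no p-value. A ratio of the 2 libraries compares those libraries. A gene was called detected at TPM of at least 1 in both. Correlations across genes used log2(TPM + 1). Expected counts were rounded to whole numbers and scaled by TMM in edgeR 4.0.16 (R 4.3.3), which also gave the common dispersion under an intercept-only design for genes at a mean of at least 10 counts. Genes beyond 2-fold had a mean of at least 50 counts, a TMM-scaled ratio above 2 in either direction and interval bounds that did not overlap after the same scaling. Size factors of DESeq2 1.42.0 were an alternative. They came out at exactly 1 in both libraries, because 922 of the 18679 genes with counts in both had equal rounded counts and the median ratio fell among them; factors from genes at a mean of at least 50 counts were therefore added after seeing the data.

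The 23 gene lists, with 294 entries, the rule for naming genes, the detection limits and most of the alternative settings were fixed before the data were examined. A list's median TPM was set against 10000 random lists of the same size, drawn from protein-coding genes at a mean TPM of at least 1, or from all annotated genes at that level for the nuclear non-coding RNAs; lists of unexpressed genes therefore sit low partly by construction. A list's median log2 ratio between the libraries, relative to the median of all genes, was set against 10000 random lists matched on expression decile. The retained-intron share is the percent of a gene's TPM in transcripts annotated as retained intron, and its list medians were set against lists matched on TPM decile. Percentiles describe these libraries only. A list below percentile 2.5 or above 97.5 is described as standing apart. For 2 list symbols with 2 entries in the annotation, Rmrp and Aldoa, the entry with the higher mean TPM was used.

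Named genes were the 5 highest and the lowest by mean TPM of the 5 response lists, the 3 highest of each other list and all sex-linked genes. They also took in the 10 genes with the highest mean TPM, the 5 largest replicate ratios per direction and the 3 largest ratios per direction between the transcript tables at TPM of at least 10. The last part was the 3 highest retained-intron shares of each response list at TPM of at least 5. Genes named outside this rule are said to be so, and a few genes within it are not reported here.

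The scripts were tested on simulated data drawn from the real means and library sizes. With 200 genes changed 4-fold between the simulated libraries, 98.5% of them and 2.67% of the unchanged among 10425 genes passed a ratio of 2, before the interval rule. A true coefficient of variation of 0.2 was returned as 0.201 without changed genes and 0.234 with them. The libraries themselves gave 0.302, a wider spread, so the 2.67% does not carry over to them. An implanted list shift of -0.7 was called in 20 of 20 lists of 16 genes among 10448 genes, and 0 of 20 lists without a shift were called. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining work. Alternatives covered the TPM limit, pseudocount, scaling, count filter, the second transcript table and each replicate on its own.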

Results

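The libraries measured RNA in the nucleoplasm of macrophages 30 min after Lipid A, a ligand of the receptor TLR4. There was 1 group with 2 libraries, of 16037242 and 14906686 expected counts, and an unstimulated sample was not analysed here. The values therefore describe levels after stimulation, and no gene can be said to have been induced. Of 55536 annotated genes, 11523 reached a TPM of at least 1 in both libraries, among them 9339 protein-coding genes and 1526 genes of long non-coding classes. Those classes take in 680 genes of class TEC, whose coding potential is unconfirmed.

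Immediate-early and feedback genes were among the abundant RNAs. Of the 24 immediate-early regulators, 23 were detected in both libraries, with a median of mean TPM of 165 against 7.94 for random lists (percentile 100). Zfp36, which promotes decay of cytokine mRNAs, stood at 466 ± 62.5 TPM (SD, n = 2), and the phosphatase genes Dusp1 and Dusp2 stood at 386 ± 61.1 and 343 ± 108 TPM. Klf6 and Junb, both transcription factor genes, reached 322 ± 64.7 and 308 ± 0.177 TPM. These SDs are of TPM, which in general was lower in replicate 2. Junb had 8317 and 10211 reads, a scaled log2 ratio of 0.36. Fosl1 was the lowest member, with 0 and 2 reads. Zfp36 (ENSMUSG00000044786.6) lies on chromosome 7 from 28376784 to 28380253 in mm10, and Dusp1 (ENSMUSG00000024190.7) on chromosome 17 from 26505590 to 26562128.

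All 16 NF-kB subunit and feedback genes were detected, with a median of 58.9 TPM (percentile 100). The median was 85.0 TPM in replicate 1 and 31.5 in replicate 2. TPM in general was lower in replicate 2, at a median log2 ratio of -0.44 over genes at a mean of at least 50 counts. The gap in TPM is therefore wider than the one relative to all genes, a median log2 ratio of -0.73. The inhibitor gene Nfkbia (ENSMUSG00000021025.8, chromosome 12, 55489410 to 55492647) stood at 631 ± 266 TPM. Tnfaip3 (ENSMUSG00000019850.11, chromosome 10, 19000910 to 19015657), which encodes the deubiquitinase A20, stood at 626 ± 246 TPM. Nfkbiz, Nfkbid and Birc3 followed at 547 ± 174, 174 ± 33.7 and 129 ± 71.1 TPM. Cyld was lowest at 14.2 ± 2.01 TPM.

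Early cytokine genes were also abundant, with 14 of 16 detected and a median of 155 TPM (percentile 100). Cxcl2 (ENSMUSG00000058427.10, chromosome 5, 90903871 to 90905938) stood at 867 ± 189 TPM and Tnf (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007) at 851 ± 148 TPM. Il1b, Tnfsf9 and Ccl4 stood at 546 ± 247, 494 ± 115 and 266 ± 101 TPM. Cxcl3 was lowest at 0.345 ± 0.262 TPM, with 13 and 8 reads.

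Genes of the later inflammatory response were low. Of 14, 4 were detected in both libraries, and the median was 0.507 TPM (percentile 0). Acod1, which makes itaconate, was the exception at 36.0 ± 29.0 TPM, followed by Ccl5 at 9.35 ± 5.88, Saa3 at 4.52 ± 2.72, Il12b at 4.43 ± 3.92 and Il27 at 1.07 ± 0.679 TPM. Il12a had 0 reads in both libraries. All 19 interferon response genes were detected, at a median of 40.6 TPM (percentile 100), with 48.1 TPM in replicate 1 and 26.1 in replicate 2. That difference takes in the generally lower TPM of replicate 2. Oasl2 and Rsad2, both antiviral genes, stood at 152 ± 40.5 and 106 ± 43.0 TPM, and Stat2 and Cxcl10 at 76.6 ± 38.4 and 67.2 ± 29.8 TPM. Ifnb1 itself had 16 and 18 reads, or 1.69 ± 0.148 TPM.

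**Figure D1:**
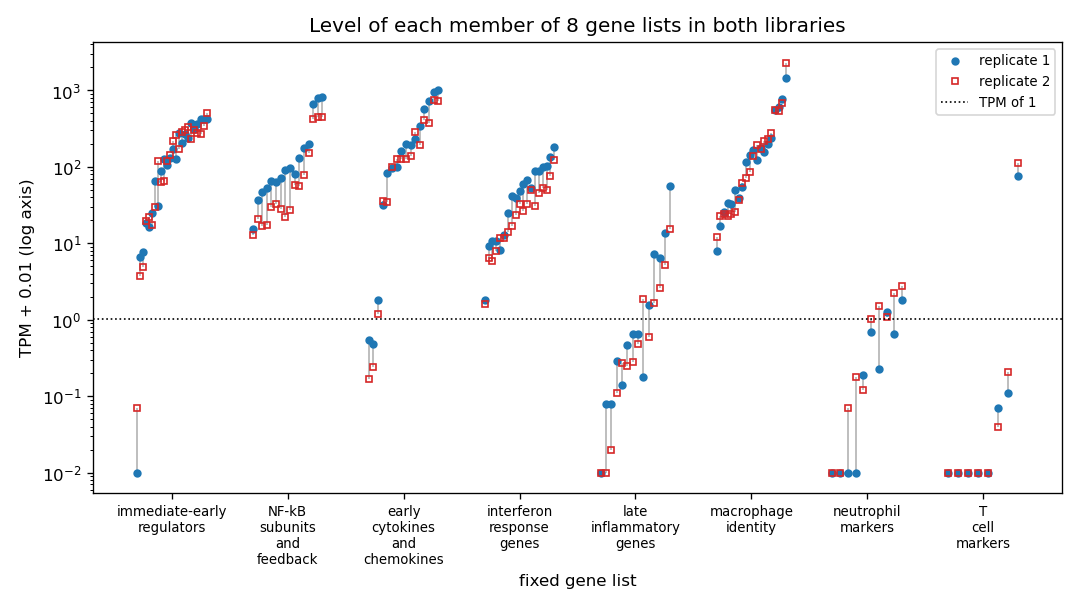
TPM plus 0.01 on a log axis for each member of 8 fixed gene lists, with filled circles for replicate 1, open squares for replicate 2 and a grey line joining both values of a gene. Most late inflammatory genes and all T cell markers but Cd28 lie under the dotted line at a TPM of 1.

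Macrophage genes were high and most other cell types were near the floor. All 20 macrophage identity genes were detected at a median of 133 TPM (percentile 100). Lyz2, which encodes lysozyme, reached 1880 ± 587 TPM, Apoe 728 ± 49.4 TPM and Csf1r, the receptor for the growth factor CSF1, 569 ± 41.5 TPM. All 18 lysosomal genes were detected at a median of 165 TPM (percentile 100), led by Psap, Ctsb and Ctsd at 4000.5 ± 238, 1672 ± 277 and 1417 ± 323 TPM. Antigen presentation, sterol metabolism and TLR4 signalling genes were all detected, with medians of 31.5, 25.7 and 17.1 TPM (percentiles 99.8, 99.0 and 97.8); in the second transcript tables the TLR4 list was at percentile 97.0 and no longer stood apart. H2-K1, H2-D1 and B2m reached 1494 ± 110, 1417 ± 351 and 308 ± 158 TPM. Abca1 and Insig1 stood at 174 ± 35.0 and 74.1 ± 13.4 TPM, and Cd14, Irf3 and Irak2 at 399 ± 45.1, 91.6 ± 27.9 and 67.4 ± 49.9 TPM.

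All 13 cytosolic housekeeping mRNAs were detected, at a median of 163 TPM (percentile 100), led by Ftl1, Fth1 and Actb at 924 ± 60.1, 808 ± 61.6 and 742 ± 308 TPM. Of 10 heat shock genes, 9 were detected at a median of 9.02 TPM (percentile 57.6), led by Hspa8, Hspa5 and Hsp90ab1 at 251 ± 3.97, 215 ± 47.5 and 66.6 ± 19.0 TPM. Of 19 cell cycle genes, 10 were detected at a median of 1.39 TPM (percentile 0). Mki67, Pcna and Top2a stood at 28.5 ± 18.3, 26.7 ± 3.90 and 3.50 ± 0.134 TPM. Alternative activation genes had a median of 1.17 TPM (percentile 0), with 4 of 11 detected. Mrc1, Il4ra and Clec10a stood at 206 ± 11.0, 35.4 ± 9.07 and 20.2 ± 1.25 TPM.

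Markers of other cell types had medians at percentile 0. B cell, fibroblast, dendritic cell and mast cell or basophil markers had 0 detected genes, with medians of 0.0225, 0.0200, 0.423 and 0 TPM. The highest B cell genes, Cd79b, Pax5 and Ms4a1, had 6 and 2, 0 and 2, and 0 and 7 reads, and the collagen genes Col1a2, Col3a1 and Col1a1 had 11 and 10, 4 and 0, and 5 and 9. Siglech, Clec9a and Zbtb46 of dendritic cells stood at 0.690 ± 0.396, 0.510 ± 0.368 and 0.475 ± 0.120 TPM. Cpa3 of mast cells had 0 and 1 reads, and Mcpt8 and Ms4a2 had 0 in both. Among neutrophil markers, at a median of 0.498 TPM, 2 of 10 were detected, and Mmp8, Ngp and S100a9 were highest at 2.26 ± 0.679, 1.44 ± 1.11 and 1.17 ± 0.106 TPM. Erythroid markers had a median of 0 TPM, with 1 of 7 detected, Alas2 at 2.24 ± 0.212 TPM; Hba-a2 had 1 and 1 reads and Klf1 had 2 and 1. Cd28 was the 1 detected T cell marker of 8, at 94.0 ± 24.2 TPM with 5106 and 9219 reads; the median of that list was 0 TPM, and Lck and Cd8a had 3 and 1 and 2 and 2 reads. Of the 6 sex-linked genes, at a median of 0 TPM, 1 was detected. Xist (ENSMUSG00000086503.4), the RNA that coats the inactive X chromosome, stood at 335 ± 230 TPM. Tsix had 15 and 2 reads. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 reads in both gene tables, which allows up to 3 counts each. The second transcript tables put 321 and 356 estimated counts on Kdm5d, 169 and 177 on Uty, 52.7 and 41.7 on Ddx3y and 15.2 and 23.1 on Eif2s3y.

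Short structural RNAs took most of the TPM. They held 62.8% ± 4.13 of TPM (SD, n = 2) and 6.12% ± 3.34 of expected counts, because TPM divides by an effective length that is small for them. Protein-coding genes held 28.4% ± 2.44 of TPM and 75.1% ± 0.253 of counts, and long non-coding RNAs, class TEC included, 6.07% ± 2.82 and 16.4% ± 3.76. The protein-coding class includes the mitochondrial mRNAs, so it overlaps the mitochondrially encoded class below. Its small spread in counts covers nuclear and mitochondrial mRNAs together, and does not hold for nuclear genes alone. Rn7sk, Rmrp and Rpph1 had the highest TPM, at 190468 ± 95022, 80689 ± 16328 and 59134 ± 41705. The near-identical Rn7s2 and Rn7s1 stood at 50021 ± 7808 and 48314 ± 10221 TPM, Malat1 at 23097 ± 4923, the snRNA gene Gm22513 at 18234 ± 2753, a second Rmrp entry at 16791 ± 12723, mt-Atp8 at 11741 ± 12780 and the snoRNA gene Gm22988 at 11734 ± 760 TPM. Malat1, a long RNA retained in nuclear speckles, took 1596750 and 1265970 reads. All 10 nuclear non-coding RNAs were detected at a median of 1045 TPM (percentile 100), with 1509 TPM in replicate 1 and 581 in replicate 2. That difference, too, takes in the generally lower TPM of replicate 2.

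The libraries differed in several RNA classes. Small and structural RNA took 3.76% of counts in replicate 1 and 8.48% in replicate 2. Most of that rise lay on Rn7sk, with 229112 and 693227 reads, and Rpph1, with 49757 and 217701. The whole class had 603178 and 1264016 reads. At a mean of at least 50 counts, the median log2 ratio was 0.61 for snRNA and -0.66 for snoRNA genes. Pseudogenes took 0.932% and 2.19%, and long non-coding RNA, lower in replicate 2, 19.1% and 13.8%. Mitochondrially encoded genes took 2.16% of counts in replicate 1 (95% Wilson interval 2.15 to 2.17) and 6.13% in replicate 2 (6.12 to 6.14). Their reads are uncertain, since nuclear pseudogene copies hold the same sequence. Together with 7 such copies, which are counted under pseudogenes, they took 2.62% and 7.87%. The pseudogene difference is therefore not separate from the mitochondrial one. Ribosomal RNA, nearly all of it from the gene CT010467.1, took 0.0981% (0.0966 to 0.0996) and 0.00939% (0.00891 to 0.00990). The second transcript tables put 90548 and 35177 estimated counts on that gene. Gm42418 overlaps it on the opposite strand, with 63257 and 22262 reads counted outside this class, so the ribosomal RNA shares and their ratio are uncertain. Ribosomal protein genes took 0.164% (0.162 to 0.166) and 0.225% (0.223 to 0.227), and replication-dependent histone genes 0.0591% (0.0580 to 0.0603) and 0.0964% (0.0948 to 0.0979).

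Across 12552 genes at a mean TPM of at least 1, Pearson's r between the libraries was 0.914 and Spearman's rho 0.900; genes are not independent replicates. The biological coefficient of variation was 0.302. Of 10448 genes at a mean of at least 50 counts, 926 had a ratio beyond 2. How many unchanged genes would pass at this spread was not simulated. Of the 926, 803 lay beyond 2-fold with separate intervals, 445 higher and 358 lower in replicate 2. The split depended on the scaling: it was 487 higher and 331 lower by library size alone, 495 higher and 324 lower with DESeq2 size factors from genes at a mean of at least 50 counts, 356 higher and 448 lower with the tied DESeq2 factors of exactly 1, and 140 higher and 1463 lower by the ratio of TPM, which moved the median of all genes from -0.03 to -0.44 on the log2 scale. Among protein-coding genes 387 were higher and 192 lower, and among transcripts of unconfirmed coding potential (class TEC), 12 were higher and 75 lower.

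The largest ratios fell on genes that overlap or copy others, and are uncertain. Gm15655, opposite Maf, had 10 and 351 reads, and Gm37401, opposite Rhoa, had 10 and 93. The adjoining mt-Atp8 and mt-Atp6 had 902 and 12005 reads and 777 and 4370 reads, and the mitochondrial copy Gm10222 had 2542 and 15287. Lower in replicate 2 were Gm26992, opposite Xist, with 762 and 0 reads (at least 243-fold lower), and Gm26759, opposite Irf2bp2, with 354 and 0 reads (at least 113-fold lower), both against a floor of 3 counts in that library. The pseudogene Gm9845 had 185 and 12 reads, and Gm25265, opposite Prex1, had 106 and 11. The ribosomal RNA gene CT010467.1, opposite Gm42418, had 15733 and 1399, while Gm42418 had 63257 and 22262. In the second transcript tables Gm26992 had 1641 and 69.5 estimated counts and Gm26759 had 342 and 63.3, so these bounds hold for the gene tables alone.

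Relative to the median of all genes, the NF-kB list was lower in replicate 2, at a median log2 ratio of -0.73 over 16 genes (percentile 0). Beyond 2-fold were 6 of the 16, all lower in replicate 2. Nfkb1, Birc3 and Traf1 are among them, with 3687 and 1528, 5424 and 2511, and 1414 and 540 reads. Late inflammatory genes were lower by the same measure, at -1.20 over 4 genes (percentile 0.04), of which Acod1 and Il12b lay beyond 2-fold, and interferon response genes at -0.38 over 18 genes (percentile 1.73). Early cytokine genes did not stand apart, at -0.06 over 13 genes (percentile 83.4). Neither did TLR4 signalling genes at -0.26 (percentile 7.21), antigen presentation at 0.08 (82.1), cell cycle at 0.48 (94.6), alternative activation at 0.34 (88.4) or nuclear non-coding RNAs at -0.29 (25.4).

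Immediate-early regulators had a higher median in replicate 2, at 0.40 over 23 genes (percentile 100), but the list was split. There were 13 members above the median of all genes and 10 below it, and by the scaled ratio itself 12 above 0 and 11 below. The median member was Junb, at a scaled log2 ratio of 0.36, and the next lower was Dusp1 at -0.01. The median therefore does not describe the list as a whole. Fos and Fosb, named after their values were seen, were the 2 beyond 2-fold, with 2970 and 8107 reads and 1620 and 7823 reads. Also higher were lysosomal genes at 0.70 over 18 genes (percentile 100), cytosolic housekeeping mRNAs at 0.55 over 13 (100), heat shock genes at 0.51 over 10 (99.0), macrophage identity genes at 0.41 over 20 (99.99) and sterol metabolism genes at 0.40 over 12 (99.8). These are ratios of 2 libraries of 1 group and carry no p-value. The random lists behind these percentiles were matched on expression alone. Among protein-coding genes the ratio also went with genomic span (Spearman's rho -0.32) and retained-intron share (-0.25). The starting RNA also differed between them.

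**Figure D2:**
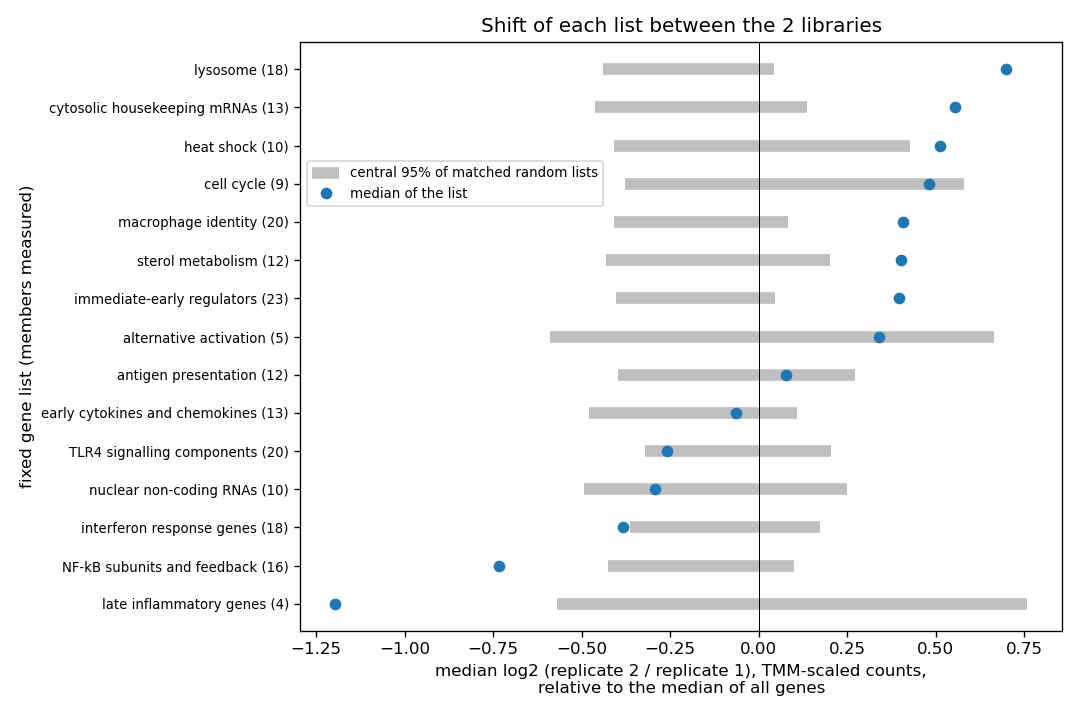
Median log2 ratio of replicate 2 over replicate 1 for 15 gene lists, relative to the median of all genes, with points for list medians and grey bars for the central 95% of matched random lists. NF-kB genes lie at -0.73 and lysosomal genes at 0.70, both outside their bars.

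Transcripts annotated as retained intron held a median of 25.5% of TPM over 6294 genes. A share of TPM gives short transcripts more weight than a share of reads does. For Cd28 in replicate 1 it was 9.21%, from 187 of 5106 reads. The share also does not separate retained introns from RNA not yet spliced. Macrophage identity genes had 2.67% (5 genes, percentile 0.035) and lysosomal genes 9.71% (13 genes, percentile 0.01), below matched lists. In the second transcript tables these shares were higher, at 4.64% (percentile 0.145) and 17.2% (percentile 1.72), and still below matched lists. Of the 5 response lists, 4 could be tested and lay within matched lists (late inflammatory genes had too few genes with such a transcript), with NF-kB genes at 31.7% (percentile 53.8), early cytokines at 34.7% (59.9), interferon response genes at 38.2% (87.2) and immediate-early regulators at 23.7% (18.7). So did TLR4 signalling genes at 31.8% (69.5), sterol metabolism at 31.6% (70.2), heat shock at 31.4% (61.2), antigen presentation at 27.1% (45.2), cytosolic housekeeping mRNAs at 22.1% (10.2), cell cycle at 15.6% (20.4) and alternative activation at 14.0% (9.11). Without replicate 2, alternative activation genes had 4.80% (percentile 0.61) and stood apart. Over the 6 genes of the main setting the replicate 1 median was 8.86%, so this call depends on which genes pass the TPM limit. The highest shares were 78.7% for Dusp1, 48.5% for Egr3 and 39.1% for Dusp2 among immediate-early genes, and 73.1% for Nfkb1, 57.1% for Nfkbie and 53.6% for Traf1 among NF-kB genes. Cxcl2, Cxcl1 and Ccl2 had 53.0%, 49.7% and 36.7%, Irf7, Oasl2 and Cmpk2 had 68.2%, 52.9% and 48.0%, and Ccl5 had 62.0%.

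The transcript tables of a library ranked protein-coding genes more alike than genes of all classes. Over 16998 genes of all classes at TPM of at least 1 in either table, Spearman's rho between their per-gene sums was 0.578 in replicate 1 and 0.607 in replicate 2, and r was 0.656 and 0.665. Over the 10708 protein-coding genes under the same filter, rho was 0.881 and 0.903. Over 9778 protein-coding genes at TPM of at least 1 in the gene table alone, a different filter, it was 0.939 and 0.948; both protein-coding sets were chosen after the result over all classes was seen. Of the 16998 genes, 3917 differed beyond 2-fold in the same direction in both libraries, 3144 higher and 773 lower in the second tables. TPM in the second tables was lower in general, at a median log2 ratio of -0.37 in replicate 1 and -0.39 in replicate 2, with a pseudocount of 1. At a mean TPM of at least 5 in either table it was -0.63 in both replicates. With TPM centred on the medians of -0.37 and -0.39, chosen after seeing the data, 4260 genes differed, 4126 higher and 134 lower. Such centring removes only part of the offset of genes at higher TPM. Most of the genes called lower thus depended on this offset. The microRNA genes Gm24270, Gm23935 and Gm24245 had 0 reads in the gene tables and 132962 TPM each in the second transcript tables. The mitochondrial pseudogenes Gm10222, Gm10925 and Gm28438 had 4818, 4331 and 1015 TPM in the gene tables and 0, 5.83 and 1.02 TPM in the second tables.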

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

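Of the tests here, the one on GC content was written before its result was seen, and all others were chosen after the pattern they address was seen. Reads were also found outside the annotated genes. Entries for phiX174, a phage genome used as a sequencing control, took 191008 reads in replicate 1 and 31781 in replicate 2, above the 3 counts that a count of 0 allows. Numbered features without a gene name took 22 and 26 reads. The 96 ERCC spike-in entries had 0 reads.

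NF-kB subunit and feedback genes were lower in replicate 2. The list stayed at percentile 0 among random lists matched on gene span, and at percentile 0 when matched on GC content, as did its 12 members with a retained-intron transcript at percentile 0 when matched on intron-containing RNA in either quantification, which argues against each as the whole cause. Dilution by cytosolic RNA stays open. The gap of 1.13 to the immediate-early list exceeded 100% of matched pairs of lists and that of 0.67 to early cytokines 97.6%. The immediate-early list was split, with 12 members above 0 and 11 below, so the gap of its median does not cover all members. Which list is less processed is also unsettled. Retained-intron shares were 23.7% for immediate-early and 31.7% for NF-kB genes in the first transcript tables and 33.2% and 25.7% in the second. In the first tables they cover 7 immediate-early and 12 NF-kB genes. Fos, Jun and Egr1, all higher in replicate 2, have no such transcript. The nuclear non-coding RNAs, which dilution would lower, went both ways and decide nothing (4 of 10 above the median of all genes and 6 below, percentile 25.4), with log2 ratios from -0.88 for Xist, -0.81 for Neat1 and -0.27 for Malat1 to 1.66 for Rn7sk and 2.19 for Rpph1; Neat1 was chosen after its values were seen. The labels give both libraries the same dose and time, starting RNA of 1 µg and 500 ng is confounded with the replicate, and no biological explanation was tested.

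Mitochondrially encoded RNA took a larger share in replicate 2. Reads shared with nuclear copies do not account for it, since genes and copies together still differed in share by a ratio of 3.005. Cytosolic carry-over cannot be told apart from other causes: ribosomal protein mRNAs were higher by 0.64 on the log2 scale relative to all genes, in the direction carry-over would give, but their level in clean nucleoplasm was not measured here. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 went the other way, with 6794 and 5285 reads and 8690 and 3761 reads, and ribosomal RNA depletion may also act on them. No biological explanation was tested.

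Cd28 stood out among T cell markers. T cell RNA as its source is argued against in the gene tables. T cells bring all their abundant transcripts, but the summed reads of the other 7 markers were at most 0.0979% of the Cd28 reads there. In the second transcript tables they came to 11.1% and 4.90% in replicates 1 and 2, mostly on Cd3d and Thy1, which had 0 reads in the gene tables. The test was first set on these summed reads with a limit of 10%, which replicate 1 exceeded in the second tables. It was changed to the median after these were seen. The median TPM of the other 7 markers was at most 0.849% of the Cd28 TPM in both libraries and quantifications. The list median of 0 TPM was already known, so the changed test adds no support. Reads from a neighbouring gene are argued against too, since the most read gene within 50 kb upstream on the same strand had at most 1.27% of the Cd28 reads. Expression of Cd28 in these macrophages stays a hypothesis.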

How the results depend on the processing

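The alternatives with centred TPM, protein-coding genes alone, genes on which both quantifications agreed, size factors from well-counted genes and nuclear copies were chosen after seeing the data; the others were planned. No paired analysis was possible because there is 1 group. Scaling alternatives multiply a library by 1 factor, so they cannot move list shifts relative to all genes. Those shifts kept their side under the ratio of TPM and on genes both quantifications put within 2-fold, for each of the 15 lists tested.

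Detected genes were 6311 at a TPM minimum of 5. Pearson's r was 0.862 and 0.793 with pseudocounts of 0.1 and 0.01, 0.955 without a filter and 0.868 at a mean TPM of at least 5; rho was 0.912 and 0.852 under these filters. The coefficient of variation was 0.280 at a mean of at least 50 counts. Genes beyond 2-fold numbered 1603 by the ratio of TPM (140 higher, 1463 lower), 1209 at a mean of at least 10 counts (707 higher), 421 at 200 (203 higher, 218 lower) and 1297 without a filter (756 higher, 541 lower); fewer or more genes entered under each filter. As shares of counts, protein-coding genes, mitochondrial mRNAs included, held 75.1%, small and structural RNA 6.12%, long non-coding RNA 16.4%, ribosomal protein genes 0.194% and histones 0.0777%, since counts are not divided by length.

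TLR4 signalling genes stood at percentile 97.0 in the second transcript tables and no longer stood apart; the cause was not tested. The 91 other list levels kept their side. Genes that differed between the transcript tables numbered 6208 with a pseudocount of 0.1, 2233 at TPM of at least 5, 1165 among protein-coding genes and 4568 to 5881 on single replicates. The 1165 protein-coding genes, from TPM that was not centred, were 573 higher and 592 lower in the second tables. The median retained-intron share was 31.7% in the second transcript table, 27.1% at TPM of at least 5 and 24.3 to 26.1% on single replicates. Alternative activation genes ranged from 4.80% to 17.7% on single replicates and stood apart at the lower value, without replicate 2. That value depends on which genes pass the TPM limit, since the 6 genes of the main setting had 8.86% in replicate 1. With 2 libraries, a value for 1 library has no error.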

Other observations

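Apart from the calls beyond 2-fold, which follow the planned rule, no test in this part was planned. The values describe 2 libraries. Among 9006 protein-coding genes at a mean of at least 50 counts, the log2 ratio of replicate 2 over replicate 1 went with genomic span, at a Spearman's rho across genes of -0.32. The 1802 genes of shortest span had a median of 0.22 and the 1801 of longest span -0.27. The correlation with retained-intron share was -0.25 over 5834 genes and with GC content -0.07. Long non-coding RNAs had a median of -0.32 over 1203 genes and ribosomal protein genes 0.61 over 82. Among mitochondrial mRNAs, named after their values were seen, mt-Nd1 had 19257 and 88670 reads, mt-Cytb 20987 and 96620, and mt-Co1 153788 and 376158. Not beyond 2-fold were mt-Nd6 with 30280 and 38086, mt-Co3 with 1890 and 3466 and mt-Nd4l with 1909 and 3513 reads. The second transcript tables put 12797 and 12513 estimated counts on mt-Co2, against 544 and 1395 reads in the gene tables.

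Single genes also differed from the rest of their list. They included Irak2, a TLR4 pathway kinase, with 2241 and 815 reads, and B2m, the light chain of MHC class I, with 2121 and 5744 reads, both beyond 2-fold. Nr1h3, which encodes the sterol sensor LXR alpha, had 569 and 174 reads. Mki67, a proliferation marker, had 6889 and 2923 reads, while Top2a had 176 and 234. Nr1h3 was chosen after its values were seen.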
